A study of Mus musculus with 15 samples.

How the data were processed

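RNA sequencing of mouse brain was analysed from the authors' deposited expression table. The labels describe 15 libraries from C57BL/6 mice and a kainic acid (KA) model of temporal lobe epilepsy. They place the libraries in 3 treatments, untreated (3 libraries), KA (6 libraries) and KA with APOE (6 libraries). The library names add a letter, L or H, which the labels do not define. The 5 groups are therefore named CTRL_L, KA_L, KA_H, APOE_L and APOE_H, with 3 libraries each. There was no untreated H group. The labels do not say whether APOE was added, deleted or otherwise changed, so the groups carry the name only. They give RNA extraction with Trizol and a TruSeq library preparation from total RNA. They do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

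The values deposited by the authors were transcript abundance as TPM, a unit already normalised for transcript length and library size, and every library summed to the same total. The aligner was STAR and the genome build was given as GRCh38, per the submitters' processing notes, with no version of the aligner. GRCh38 is a human assembly, whereas the identifiers in the table were mouse Ensembl genes. The quantification tool, the annotation release and the strand setting were not given in the sources used here. The table held 65964 entries. Of these, 55416 were mouse Ensembl identifiers and 10548 were assembled loci with MSTRG names, which carry no gene name. Whether they overlap named genes was not examined. Symbols were taken by identifier from the GENCODE M21 annotation (GRCm38), which matched 52083 of the Ensembl identifiers and left 3333 without a symbol. Where entries shared a symbol, the symbol went to the more abundant and the other 68 kept their identifier. No coordinates are given, because the build named in the notes and the build of the annotation differ. TPM values keep no sequencing depth, so the number of reads behind each value is unknown and no counting interval is given. No count model was used for the same reason. No pair of libraries held identical values.

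An exact 0 in a TPM table can be a failed estimate. Among 30 genes used by every cell, Pgk1 was listed at 0 in 2 libraries (CTRL_L replicate 1 and APOE_L replicate 1), where its other values ran from 0.09 to 257 TPM. Snrpd3 was also listed at 0 in 2 libraries (CTRL_L replicate 2 and APOE_L replicate 1). A gene at 0 is therefore described as listed at 0, with the value of each library in place of a mean and SD.

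Tests were run on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend). All 15 libraries entered 1 fit with a mean per group, which left 10 residual degrees of freedom and a median prior of 6.67. Entries at 1 TPM or more in at least 3 of the 15 libraries were tested. These were 17505 entries, of which 14029 had a symbol, 3243 were assembled loci and 233 were identifiers without a symbol; 11865 were annotated as protein-coding. The pseudocount of 1 compresses low values, so a log2 fold change understates the change of a gene near 0. The 8 comparisons were KA_L with CTRL_L, KA_H with KA_L, KA_H with CTRL_L, APOE_L with KA_L, APOE_H with KA_H, APOE_H with APOE_L, APOE with KA averaged over both letters, and the interaction of condition and letter. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Means are given with the SD over 3 libraries, and log2 fold changes with their standard error (SE). For Apoe, an exact two-sided permutation test of TPM was added. With 3 libraries against 3 such a test cannot go below 0.1.

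Gene lists, 37 in number, were fixed together with the tests, the named-gene rule and the alternative settings before the data were examined. They covered markers of brain, vascular, choroid plexus and blood cell types, reactive astrocyte genes, lipid and cholesterol handling, glutamate, potassium and adenosine handling, immediate early, inflammatory and microglial genes, lysosome, energy metabolism, stress responses, cell cycle, synapse, ion channel and extracellular matrix genes. Lists with at least 3 tested members were compared with all other tested entries by camera with a preset inter-gene correlation of 0.01. This left 34 lists, adjusted over lists within a comparison. Each list was also run with the correlation estimated from the data and with fry, which asks whether its genes move one way and does not compare them with other genes. Counts of called members are given over all tested entries and adjusted over the list alone. Lists overlap; of the 20 disease-associated microglia genes, 10 are also in another list.

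Named genes followed a fixed rule. Per comparison these were Apoe, up to 10 genes each with the largest positive and negative log2 fold change that passed the threshold, had no overlap between the replicate values of the groups and had a mean of at least 5 TPM in the higher group, and up to 4 members with the smallest p of each list that passed camera or had at least 3 called members. Predicted gene models and pseudogenes were left out, and members that did not pass may be named as such. With 3 libraries against 3, chance gives non-overlapping groups for 10% of genes. Where few genes passed in a comparison, those outside the rule are also named, as chosen after their values were seen. Some genes that the rule names are not reported here.

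Alternatives planned in advance were pseudocounts of 0.1 and 5, no filter and a stricter filter (5 TPM), upper-quartile scaling, quantile normalization, rescaling without mitochondrially encoded genes, fits of the compared groups alone, no mean-variance trend, array weights, the replicate number as a block, each library left out in turn, a fold-change threshold, an estimated correlation and fry. Added after the data were seen were rescaling over named genes, rescaling over nuclear protein-coding genes, and only genes at 5 TPM or more in every group compared. Overlaps between comparisons that share libraries were set against 100 simulations of unchanged groups.

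The fit was tested on simulated data before use. In a simulated comparison of KA_H with KA_L over 17505 genes, with 200 changed and the spread of each gene in the real libraries, 1% of genes changed by 2 on the log2 scale and 19% of those changed by 4 were recovered, and 0 unchanged genes were called. Genes were drawn independently, which leaves out variation shared by many genes of a library. The 0 therefore does not carry over to the real libraries, where a wrong split of KA_L and CTRL_L gave up to 38 calls. In the real comparisons the median absolute log2 fold change of the called genes lay between 2.23 and 5.50. Files were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1) and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.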

Results

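Gene expression was measured by RNA sequencing in 15 libraries from mouse brain, in transcript abundance scaled to library size and transcript length (TPM). Kainic acid (KA), an agonist of kainate-type glutamate receptors, is widely used to induce status epilepticus and chronic seizures in rodents. Groups of 3 libraries each were controls (CTRL_L), treated with KA (KA_L and KA_H) or treated with KA in the APOE condition (APOE_L and APOE_H). The letters L and H are given in the library names without a definition. The series concerns lipid-laden reactive astrocytes in epilepsy and the part that apolipoprotein E plays there. The comparisons accordingly asked what differed after KA, between H and L, and between the APOE condition and KA alone.

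Microglial transcripts were abundant in each of the 15 libraries, whereas most astrocyte, neuronal and oligodendrocyte lineage transcripts were near 0. All 18 microglia markers reached 1 TPM in each library. The purinergic receptor gene P2ry12 ran from 878 to 9373 TPM. The highest mean over the 15 libraries was that of Cst3, encoding cystatin C, at 36834 TPM. Among 20 astrocyte markers, 6 passed the expression filter and 1, the glutamate transporter gene Slc1a3, reached 1 TPM in each library (33.5 to 157 TPM). Gfap, the astrocyte intermediate filament gene, was listed at 0 in 11 libraries and did not exceed 3.53 TPM in the others. The water channel gene Aqp4 was listed at 0 in 7 libraries and was highest in APOE_L replicate 1, at 53.5 TPM. The filter passed 2 of 20 neuron markers, 8 of 14 oligodendrocyte markers, 0 of 10 oligodendrocyte precursor markers and 2 of 14 mural and fibroblast markers.

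The H and L libraries also differed in how many entries reached 1 TPM. Entries at 1 TPM or more numbered 13461 ± 236 (mean ± SD, n = 3) in KA_H and 14026 ± 1337 in APOE_H, against 10843 ± 1114 in KA_L, 10672 ± 540 in APOE_L and 10890.0 ± 256 in CTRL_L. Entries above 0 went the other way after KA, with 19552 ± 502 in KA_L and 18944 ± 353 in APOE_L against 18350.3 ± 445 in KA_H and 17645 ± 1205 in APOE_H, and were fewest in CTRL_L (16673 ± 849). Assembled loci without a gene name held 11.8 ± 0.362% of the total in KA_L and 11.03 ± 0.414% in APOE_L, and 5.46 ± 1.18% in KA_H and 2.83 ± 0.542% in APOE_H. CTRL_L lay between them at 7.84 ± 1.11%. Spearman correlations between libraries of a group, taken across genes, ran from 0.498 to 0.520 in CTRL_L, 0.522 to 0.525 in KA_L, 0.543 to 0.555 in APOE_L, 0.599 to 0.629 in KA_H and 0.684 to 0.777 in APOE_H. Between groups they ran from 0.321 (KA_L replicate 1 with APOE_H replicate 3) to 0.663 (KA_H replicate 3 with APOE_H replicate 1). KA_L replicate 2 stood at 0.537 with CTRL_L replicate 1 and 0.565 with APOE_L replicate 3. Only in APOE_H did each value within the group exceed all of those between groups. The first principal component, with 20.2% of the variance, placed the H libraries between 28.5 and 176 and the L libraries between -147 and -0.80.

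**Figure D1:**
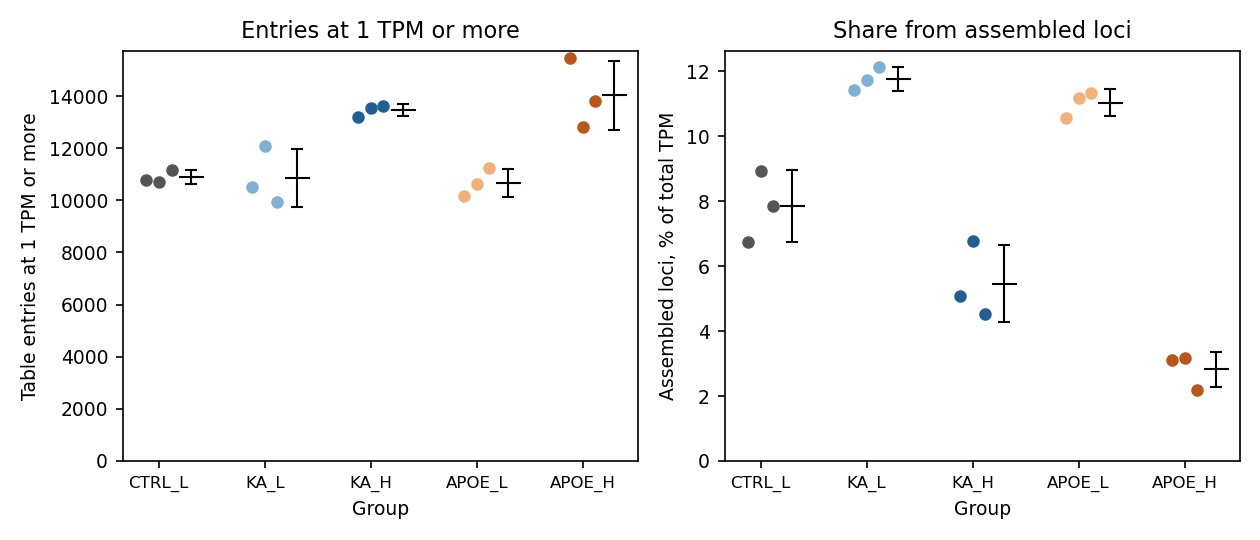
Number of table entries at 1 TPM or more (left) and share of the summed TPM from assembled loci (right) in each of the 15 libraries; points are libraries and black marks the mean ± SD of 3. The 6 H libraries lie at 12801 entries or above and the 9 L libraries at 12085 or below.

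Apoe, encoding the main lipid carrier protein of the brain, differed between the groups more than any other gene in the averaged comparison. It stood at 535 ± 364 TPM in CTRL_L, 2772 ± 701 in KA_L and 11947 ± 4146 in KA_H (mean ± SD, n = 3). In APOE_L the libraries were at 0.69, 0.71 and 0 TPM, the last being listed at 0, and in APOE_H at 144, 6.49 and 12.4 TPM. Averaged over both letters, Apoe fell by 9.89 on the log2(TPM + 1) scale in the APOE condition (SE 0.62, adjusted p = 2.52e-07, limma with Benjamini-Hochberg adjustment; lower in 6 of 6 libraries). The exact permutation test over 6 against 6 libraries gave p = 0.00216, the smallest it can give. Between CTRL_L and KA_H, which differ in both treatment and letter, Apoe was higher in KA_H, with a ratio of means of 22.3 (log2 fold change 4.74, SE 0.87, adjusted p = 0.0307, limma). The differences in treatment or letter alone did not pass by limma, KA_L against CTRL_L (log2 fold change 2.65, adjusted p = 0.241) and KA_H against KA_L (2.09, adjusted p = 0.268). The SE was 0.87 in both, because the fit takes 1 spread from all 15 libraries. That spread includes APOE_H, which ran from 6.49 to 144 TPM. Values did not overlap between CTRL_L (161 to 889 TPM), KA_L (1970 to 3262 TPM) and KA_H (8767 to 16636 TPM). In the APOE condition Apoe was higher in APOE_H than in APOE_L (log2 fold change 4.10, SE 0.87, adjusted p = 0.0119, limma). Each exact permutation test of 3 libraries against 3 gave p = 0.1, the smallest possible. The labels do not say what was done to APOE, so the level is given as measured in the libraries labelled APOE.

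**Figure D2:**
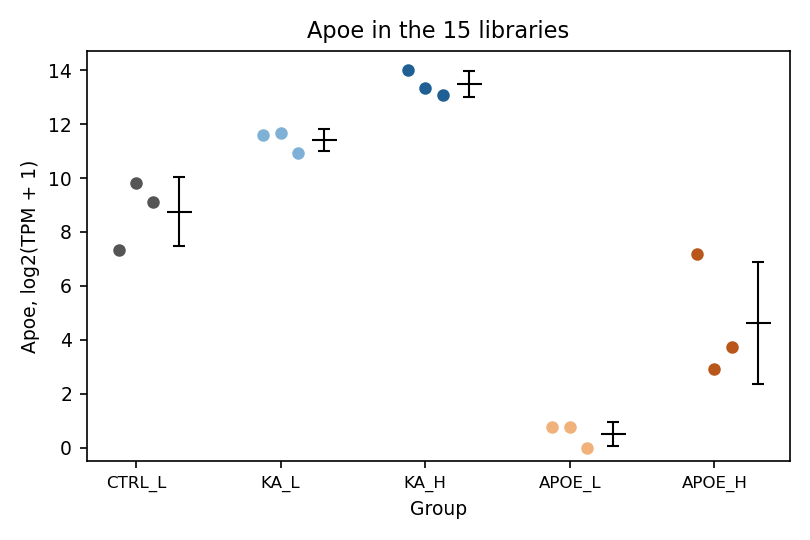
Apoe as log2(TPM + 1) in each of the 15 libraries by group; points are libraries and black marks the mean ± SD of 3. Libraries labelled APOE lie below 145 TPM and KA libraries at 1970 TPM or above.

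KA_L was compared with CTRL_L to show what differed after KA within the L libraries. Of 20 disease-associated microglia genes 4 rose and 16 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.217). Cst7, a lysosomal cysteine protease inhibitor, rose from 0.133 ± 0.0751 to 331 ± 13.5 TPM (n = 3; log2 fold change 8.20, SE 0.53, adjusted p = 4.15e-07, limma with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Spp1, encoding the secreted protein osteopontin, went from 0.203 ± 0.217 to 194 ± 129.7 TPM (adjusted p = 0.0139, limma), and Lpl, a triglyceride-hydrolysing lipase, from 0.467 ± 0.456 to 34.1 ± 15.3 TPM (adjusted p = 0.0278, limma). The chemokine genes Ccl3 (935 ± 572 to 3767 ± 737 TPM) and Ccl4 (666 ± 194 to 2609 ± 1055 TPM) rose by 2.20 and 1.94 on the log2 scale (adjusted p = 0.0274 and 0.0376, limma). Ccl2 stood at 92.1 ± 29.8 and 493 ± 232 TPM and missed the threshold (adjusted p = 0.0690, limma).

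Among the genes that fell in KA_L, several were close to 0 in all 3 of its libraries. H2-Aa, which encodes an MHC class II chain, stood at 123, 32.4 and 629 TPM in CTRL_L and 0.1, 0.09 and 0.13 TPM in KA_L (adjusted p = 0.00552, limma). H13, encoding signal peptide peptidase, went from 162 ± 92.4 to 0.213 ± 0.0751 TPM, and Churc1 from 326 ± 256 to 2.29 ± 1.45 TPM (adjusted p = 0.00411 and 0.000503, limma). Cops6, a COP9 signalosome subunit gene, was at 122, 158 and 202 TPM in CTRL_L and 0, 0.41 and 0.08 in KA_L (adjusted p = 0.0139, limma). Eno1, a glycolytic enolase gene, fell from 228 ± 120.1 to 16.5 ± 18.2 TPM, and mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, from 4852 ± 905 to 1751 ± 660.2 TPM (adjusted p = 0.0421 and 0.0193, limma).

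By group, 4 of 20 disease-associated microglia genes (Cst7, Spp1, Lpl and Csf1) rose and 16 did not pass, with 8 higher adjusted over the list alone (median log2 fold change 1.25, camera adjusted p = 3.20e-07; adjusted p = 0.217 with an estimated correlation). Inflammatory cytokines and chemokines had 3 of 23 members higher and 5 adjusted over the list alone (camera adjusted p = 0.00140; adjusted p = 0.222 with an estimated correlation). Interferon response genes had none of 22 called and 0 adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.0480; adjusted p = 0.522 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes lay lower, with none of 32 called, 5 lower adjusted over the list alone and a median of -1.36 (camera adjusted p = 3.20e-07; adjusted p = 0.217 with an estimated correlation). Glycolysis genes had 1 of 21 lower and 6 adjusted over the list alone (camera adjusted p = 3.77e-05; adjusted p = 0.217 with an estimated correlation). Mitochondrially encoded genes had 1 of 12 lower and 1 adjusted over the list alone, and lysosome genes none of 23 and 0 (camera adjusted p = 7.90e-05 and 0.0130; adjusted p = 0.498 and 0.387 with an estimated correlation). Choroid plexus markers moved with the same groups, with 0 of 10 called, 3 lower adjusted over the list alone and a median of -3.34 (camera adjusted p = 7.90e-05; adjusted p = 0.382 with an estimated correlation). Ttr, the choroid plexus thyroid hormone carrier, was at 54.1, 20666 and 10235 TPM in the CTRL_L libraries and 31.6, 781 and 114 in KA_L. Assembled loci held more of the total in KA_L (11.8 ± 0.362%) than in CTRL_L (7.84 ± 1.11%). Protein-coding genes held less (74.4 ± 0.648% against 80.4 ± 2.64%). Whether intronic or genomic background bears on this comparison was not tested.

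In all, 100 genes differed between KA_L and CTRL_L, 30 higher and 70 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 1945 had an unadjusted p under 0.05 where chance gives 875. The count was 232 without CTRL_L replicate 1, 210 without KA_L replicate 2 and 66 without CTRL_L replicate 2. It was 0 when those 6 libraries were fitted alone, and upper-quartile scaling gave 26 higher and 36 lower.

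KA_H was compared with KA_L to show what differed between the letters after KA. The choroid plexus genes Ttr and Enpp2 were among those higher in KA_H. Ttr rose from 309 ± 411 to 25271 ± 2468 TPM and Enpp2, a lysophospholipase secreted by choroid plexus, from 187 ± 257 to 10272 ± 1635 TPM (n = 3; log2 fold change 7.46, SE 1.79, adjusted p = 0.0481 and 6.85, SE 1.38, adjusted p = 0.0245, limma with Benjamini-Hochberg adjustment; both higher in 3 of 3 libraries). B2m, the MHC class I light chain, rose from 8191 ± 410.2 to 24697 ± 5082 TPM, and Cd74, the MHC class II invariant chain, from 38.2 ± 19.9 to 896 ± 683 TPM (adjusted p = 0.00533 and 0.0366, limma). Tyrobp, a microglial signalling adaptor, rose from 5344 ± 1524 to 13096 ± 2319 TPM and Itgax, encoding CD11c, from 0.647 ± 0.579 to 56.6 ± 12.6 TPM (adjusted p = 0.0227 and 0.0260, limma). Fos, the immediate early transcription factor gene, fell from 2131 ± 328 to 588 ± 103 TPM (log2 fold change -1.86, SE 0.32, adjusted p = 0.00974, limma).

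The respiratory chain gave some of the smallest p-values. Ndufa1, a complex I subunit gene, rose from 308 ± 166 to 3774 ± 1179.8 TPM, Cox6a1 from 303 ± 181 to 1704 ± 353 TPM and mt-Co1 from 1751 ± 660.2 to 8191 ± 1056 TPM (adjusted p = 0.00533, 0.00590 and 0.000937, limma). The neutrophil genes S100a8 and S100a9 were listed at 0 in the 3 KA_L libraries and stood at 457, 873 and 129 TPM and 354, 399 and 96.4 TPM in KA_H (adjusted p = 0.0256 and 0.0296, limma). Kcnj13, a potassium channel gene of choroid plexus, was at 0.05, 0.01 and 0 TPM in KA_L and 779, 1125 and 1303 in KA_H (adjusted p = 0.00894, limma). Lower in KA_H were Rny3, a Y RNA gene (647 ± 301 to 52.0 ± 86.5 TPM), Inpp4b, a phosphoinositide phosphatase gene (574 ± 160.5 to 32.3 ± 12.7 TPM), and Clasp1, a microtubule plus-end protein gene (158 ± 31.7 to 4.22 ± 0.626 TPM), with adjusted p = 0.0405, 0.0142 and 0.00827 by limma.

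Of the 34 tested lists 18 passed camera, and none passed with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 6 of 32 higher, 22 adjusted over the list alone and a median of 1.72 (camera adjusted p = 3.41e-12; adjusted p = 0.0569 with an estimated correlation). Mitochondrially encoded genes had 3 of 12 higher and 9 adjusted over the list alone (camera adjusted p = 7.84e-08; adjusted p = 0.169 with an estimated correlation). Disease-associated microglia genes had 6 of 20 higher and 13 adjusted over the list alone (camera adjusted p = 1.18e-09; adjusted p = 0.101 with an estimated correlation). Choroid plexus markers had 4 of 10 higher, 8 adjusted over the list alone and a median of 5.45 (camera adjusted p = 7.84e-08; adjusted p = 0.116 with an estimated correlation). Complement and antigen presentation genes had 4 of 21 higher, with 9 higher and 1 lower adjusted over the list alone, and oxidative stress genes 4 of 21 higher and 6 adjusted over the list alone (camera adjusted p = 4.74e-05 and 0.000428; adjusted p = 0.148 and 0.0569 with an estimated correlation). Immediate early genes lay lower, with 1 of 16 (Fos) called and 4 adjusted over the list alone (camera adjusted p = 2.27e-05; adjusted p = 0.108 with an estimated correlation).

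Smaller groups followed. Lysosome genes (2 of 23 higher, 3 adjusted over the list alone), glycolysis genes (2 of 21, 5 adjusted over the list alone) and fatty acid oxidation genes (2 of 22, 3 adjusted over the list alone) had camera adjusted p = 3.26e-05, 0.000792 and 0.00123 (adjusted p = 0.106, 0.106 and 0.106 with an estimated correlation). Lists of other cell types passed camera beside them. Leukocyte markers (3 of 10 higher, 4 adjusted over the list alone), endothelial markers (0 of 11, 1 adjusted over the list alone) and red blood cell markers (0 of 4, 2 adjusted over the list alone) had camera adjusted p = 0.00314, 0.000792 and 0.00430 (adjusted p = 0.106, 0.146 and 0.208 with an estimated correlation). Cytokine, cell cycle, pan-reactive astrocyte, interferon and A2 astrocyte genes passed camera with adjusted p = 0.0221, 0.0250, 0.0267, 0.0403 and 0.0403 (adjusted p = 0.186, 0.255, 0.108, 0.431 and 0.169 with an estimated correlation). Of these lists, 1 cell cycle gene (Birc5) and 1 A2 gene (Tm4sf1, listed at 0 in KA_L) rose, against 1 and 2 adjusted over the list alone. Adjusted over the list alone, 1 interferon gene was higher and 1 lower, and 0 cytokine and 0 pan-reactive genes were called.

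KA_H and KA_L differed in 260 genes, 216 higher and 44 lower (limma, Benjamini-Hochberg), with 2595 at an unadjusted p under 0.05. Of the 216 higher genes, 156 (72.2%) were under 1 TPM in at least 2 of the 3 KA_L libraries. The count fell to 98 and 95 without KA_L replicate 1 or 3, and to 82, 132 and 38 without KA_H replicate 1, 2 or 3. It was 3 when the 6 libraries were fitted alone and 106 among genes at 5 TPM or more in both groups, and the median log2 fold change of all genes moved from 0.11 to 0.32 with upper-quartile scaling and to -0.11 with quantile normalization.

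KA_H was set against CTRL_L, the sole control group, although the letters differ. Disease-associated microglia genes had the smallest camera adjusted p of all lists and comparisons. Cst7 rose from 0.133 ± 0.0751 to 1597 ± 506 TPM and Spp1 from 0.203 ± 0.217 to 1595 ± 766 TPM (n = 3; log2 fold change 10.42, SE 0.53, adjusted p = 9.23e-09 and 10.27, SE 1.23, adjusted p = 0.00200, limma with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Clec7a, encoding the pattern receptor dectin-1, was at 0, 0 and 0.02 TPM in CTRL_L and 637, 318 and 573 in KA_H (adjusted p = 0.00329, limma). B2m rose from 6622 ± 1558 to 24697 ± 5082 TPM, the interferon-induced gene Ifitm3 from 37.3 ± 32.2 to 1242 ± 464 TPM, and the lysozyme gene Lyz2 from 371 ± 195 to 3120.5 ± 995 TPM (adjusted p = 0.00238, 0.0252 and 0.0303, limma). Csmd3, a large transmembrane protein gene, fell from 496 ± 144 to 51.6 ± 24.6 TPM and the zinc finger gene Zfp592 from 154 ± 24.4 to 2.85 ± 4.82 TPM (adjusted p = 0.0293 and 0.0357, limma).

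All 20 disease-associated microglia genes had a positive fold change, 9 of them rose and 11 did not pass, and 17 were higher adjusted over the list alone (median 3.13, camera adjusted p = 4.42e-30). Inflammatory cytokines and chemokines, among them Ccl3 at 4422 ± 1235 and Ccl4 at 3175 ± 1228 TPM in KA_H, had 3 of 23 higher and 11 adjusted over the list alone (camera adjusted p = 1.22e-09). These 2 of the 16 lists that passed camera also passed with an estimated correlation (adjusted p = 0.00580 and 0.0157 with an estimated correlation). Lipoprotein and cholesterol transport genes had 3 of 20 higher (Apoe, Lpl and Apoc1) and 5 adjusted over the list alone (camera adjusted p = 0.00697; adjusted p = 0.0880 with an estimated correlation). Interferon genes had 1 of 22 higher and 3 adjusted over the list alone, and complement and antigen presentation genes 1 of 21 and 1 (camera adjusted p = 6.91e-06 and 4.03e-05; adjusted p = 0.135 and 0.142 with an estimated correlation). Pan-reactive astrocyte genes had 0 of 6 called and 2 adjusted over the list alone, and cell cycle genes 0 of 18 and 1 (camera adjusted p = 0.00372 and 0.000979; adjusted p = 0.0880 and 0.142 with an estimated correlation). Immediate early genes lay lower by camera, with 0 of 16 called and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.000497; adjusted p = 0.143 with an estimated correlation).

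Lists of other cell types passed camera here as well, none of them with an estimated correlation. Leukocyte (2 of 10 higher, 3 adjusted over the list alone), endothelial (0 of 11, 1 adjusted over the list alone) and red blood cell markers (0 of 4, 4 adjusted over the list alone) had camera adjusted p = 0.00127, 0.000435 and 0.000497 (adjusted p = 0.0915, 0.135 and 0.143 with an estimated correlation). The mean log2 level of the endothelial list was 3.46, 3.10 and 6.11 in the 3 KA_H libraries. Choroid plexus markers had 0 of 10 called, 0 adjusted over the list alone and camera adjusted p = 0.0143 (0.465 as adjusted p with an estimated correlation), and without CTRL_L replicate 1 camera gave an adjusted p of 0.842 in the other direction. Oxidative phosphorylation, fatty acid oxidation, mitochondrially encoded and oxidative stress genes passed camera with adjusted p = 0.00322, 0.0115, 0.0115 and 0.0459 (adjusted p = 0.256, 0.135, 0.494 and 0.135 with an estimated correlation). None of their members was called over all genes, and 4, 1, 0 and 1 were higher adjusted over the list alone. The mitochondrially encoded list pointed the other way under quantile normalization (camera adjusted p = 0.937).

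The comparison called 66 genes, 55 higher and 11 lower (limma, Benjamini-Hochberg), with 1830 at an unadjusted p under 0.05. The count was 43 and 35 without CTRL_L replicate 2 or 3 and 29, 32 and 17 without KA_H replicate 1, 2 or 3, and 3 when the 6 libraries were fitted alone. Upper-quartile scaling moved the median log2 fold change of all genes from 0.10 to 0.47.

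**Figure D3:**
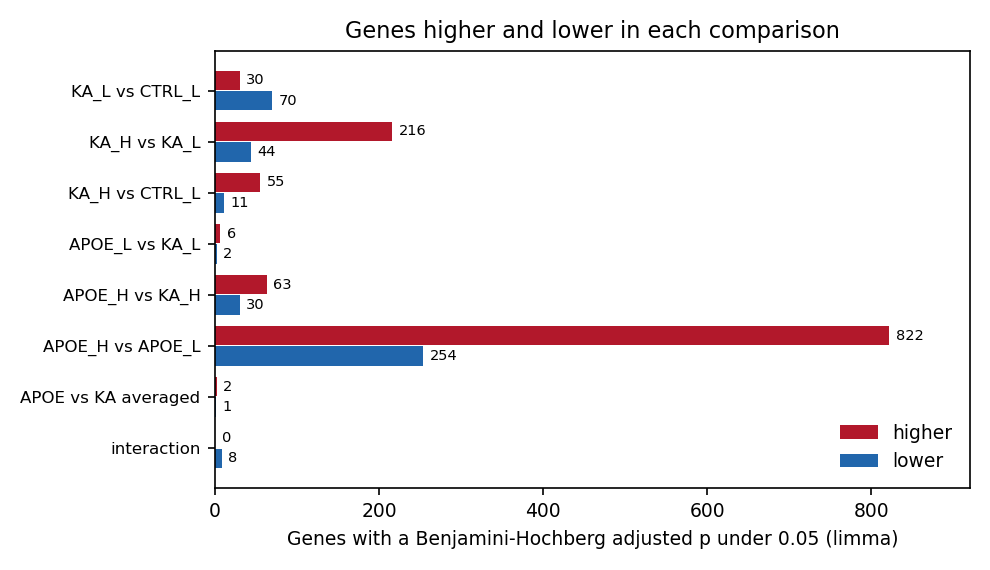
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 by limma in each of the 8 comparisons, higher in red and lower in blue; 17505 entries were tested in each. Calls run from 3 in the averaged APOE comparison to 1076 between APOE_H and APOE_L.

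APOE_L was compared with KA_L to show what differed in the APOE condition within the L libraries. Few genes besides Apoe passed the threshold. In the simulated comparison of groups of this size, 19% of genes changed by 4 on the log2 scale were recovered. Tmem147, a gene for an endoplasmic reticulum membrane protein, was at 0, 0.47 and 0 TPM in KA_L and 181, 314 and 81.5 in APOE_L (log2 fold change 7.21, SE 0.75, adjusted p = 0.000307, limma with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). H2-Aa rose from 0.107 ± 0.0208 to 121 ± 144 TPM and Churc1 from 2.29 ± 1.45 to 131 ± 77.3 TPM (adjusted p = 0.0468 and 0.00508, limma). The proteasome subunit gene Psmb5 (0, 1.74 and 0.12 TPM in KA_L, 56.4, 87.7 and 89.0 in APOE_L) and Tmem11, of the mitochondrial inner membrane (0.25, 0.19 and 0 and 50.3, 29.8 and 43.8 TPM), also rose (adjusted p = 0.0374 and 0.0374, limma). Apoe fell by 10.89 on the log2 scale (adjusted p = 1.19e-05, limma). The other 2 of the 8 calls were an assembled locus and the predicted gene Gm37728, named after their values were seen; the latter was at 13.2, 22.9 and 33.7 TPM in KA_L and listed at 0 in the 3 APOE_L libraries.

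Mitochondrially encoded genes lay higher in APOE_L, all 12 with a positive fold change, none called over all genes and 9 adjusted over the list alone (median 0.86, camera adjusted p = 5.07e-12; adjusted p = 0.461 with an estimated correlation). Among them, mt-Atp6 stood at 13021 ± 2800.2 TPM in KA_L and 27488 ± 5031 in APOE_L (adjusted p = 0.203, limma). Complement and antigen presentation genes had 1 of 21 higher and 2 adjusted over the list alone, microglia markers 0 of 18 and 0, and leukocyte markers 0 of 10 and 1 (camera adjusted p = 0.000617, 0.00335 and 0.0170; adjusted p = 0.461, 0.686 and 0.461 with an estimated correlation). Immediate early genes lay lower, with 16 of 16 fold changes negative, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00537; adjusted p = 0.461 with an estimated correlation). Disease-associated microglia genes without Apoe differed by 0.02 in mean log2 level (95% interval -0.86 to 0.89, APOE_L minus KA_L, linear model over the 15 libraries, 19 genes).

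In total 8 genes passed, 6 higher and 2 lower (limma), and 1373 had an unadjusted p under 0.05 where chance gives 875. The count was 16, 68 and 32 without KA_L replicate 1, 2 or 3, 20 without APOE_L replicate 3, and 0 among genes at 5 TPM or more in both groups. The balance turned with a pseudocount of 5 (2 higher and 3 lower), without KA_L replicate 1 (5 higher and 11 lower) and without KA_L replicate 3 (12 higher and 20 lower), while rescaling over nuclear protein-coding genes, an alternative added after the data were seen, gave 6 higher and 1 lower.

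APOE_H was compared with KA_H to show what differed in the APOE condition within the H libraries. Apoe fell by 8.88 on the log2 scale, and the neighbouring apolipoprotein gene Apoc2 was at 61.7, 53.3 and 42.9 TPM in KA_H and 3.48, 0 and 0 in APOE_H (adjusted p = 0.000247 and 0.00958, limma with Benjamini-Hochberg adjustment; both lower in 3 of 3 libraries). Acaca, encoding the acetyl-CoA carboxylase that opens fatty acid synthesis, fell from 1658 ± 374 to 555 ± 23.4 TPM (log2 fold change -1.55, SE 0.23, adjusted p = 0.00762, limma). The translation factor gene Eif4g3 (6714 ± 1146 to 2228 ± 131 TPM), Mllt6 (2974 ± 512 to 854 ± 220.1 TPM) and mt-Cytb (11920.3 ± 2189 to 4819 ± 1424 TPM) also fell (adjusted p = 0.00260, 0.00958 and 0.0301, limma). Acaca, Eif4g3 and Mllt6 were also called lower in H in both H against L comparisons. Assembled loci held 5.46% of the total in KA_H and 2.83% in APOE_H. Whether intronic or genomic background contributes to these falls was not tested. Ctsd, the lysosomal protease cathepsin D, rose from 4167 ± 701 to 20400.4 ± 8829 TPM, the chaperone gene Hspa8 from 341 ± 89.6 to 1147 ± 19.8 TPM and the phosphatase gene Dusp1 from 402 ± 29.9 to 1341 ± 329 TPM (adjusted p = 0.0167, 0.0439 and 0.0286, limma). The largest positive fold changes were of genes near 0 in KA_H, such as Tmem184a, at 0, 0.05 and 0 TPM there and 18.1, 17.8 and 12.8 in APOE_H (adjusted p = 0.00762, limma).

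Mitochondrially encoded genes lay lower, with 2 of 12 called and 12 adjusted over the list alone (median -1.07, camera adjusted p = 1.79e-19; adjusted p = 0.0969 with an estimated correlation). Lysosome genes had 1 of 23 higher and 6 adjusted over the list alone, and glycolysis genes 0 of 21 and 7 (camera adjusted p = 1.41e-07 and 1.25e-06; adjusted p = 0.0969 and 0.0969 with an estimated correlation). Immediate early genes had 1 of 16 higher and 5 adjusted over the list alone, unfolded protein response genes 0 of 15 and 2, and heat shock genes 1 of 11 and 1 (camera adjusted p = 0.00116, 0.00116 and 0.0376; adjusted p = 0.208, 0.207 and 0.208 with an estimated correlation). Cholesterol synthesis genes had none of 20 called and 0 adjusted over the list alone, at a median of 1.64 (camera adjusted p = 0.0143; adjusted p = 0.0969 with an estimated correlation). A1 astrocyte genes had 0 of 12 called and 3 adjusted over the list alone, adenosine signalling genes 1 of 7 (Nt5e, listed at 0 in KA_H) and 2, and complement and antigen presentation genes 0 of 21 called with 3 higher and 1 lower over the list alone (camera adjusted p = 0.0143, 0.0152 and 0.00547; adjusted p = 0.125, 0.0969 and 0.370 with an estimated correlation). Red blood cell markers lay lower, with 0 of 4 called and 0 adjusted over the list alone (camera adjusted p = 0.0434; adjusted p = 0.403 with an estimated correlation). Disease-associated microglia genes did not pass camera (adjusted p = 0.977).

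The H libraries of the 2 conditions differed in 93 genes, 63 higher and 30 lower (limma, Benjamini-Hochberg), and 1510 had an unadjusted p under 0.05. The count was 50 without KA_H replicate 2 and 55 without APOE_H replicate 3, and 0 when the 6 libraries were fitted alone. Among genes at 5 TPM or more in both groups 0 were higher and 4 lower, and with no filter 2 were higher and 2 lower. Ctsd, Hspa8 and Dusp1 were not called in either (adjusted p = 0.0602, 0.159 and 0.113 at 5 TPM or more in APOE_H against KA_H, limma). Quantile normalization gave 10 higher and 15 lower and upper-quartile scaling 54 higher and 47 lower, moving the median log2 fold change of all genes from 0.25 to -0.02 and 0.01.

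APOE_H was compared with APOE_L to show what differed between the letters in the APOE condition. Choroid plexus transcripts again stood at opposite levels. Ttr rose from 109 ± 97.0 to 34654 ± 8983 TPM and Enpp2 from 107 ± 11.9 to 15089 ± 2736 TPM (n = 3; log2 fold change 9.72, SE 1.79, adjusted p = 0.00629 and 7.11, SE 1.38, adjusted p = 0.00785, limma with Benjamini-Hochberg adjustment; higher in 3 of 3 libraries). Lysosomal protease genes rose, Ctsd from 1967 ± 406 to 20400.4 ± 8829 TPM and Ctsb from 754 ± 302 to 6047 ± 1631 TPM (adjusted p = 0.000417 and 0.00327, limma). In lipid metabolism, the sterol oxidase gene Msmo1 rose from 2.82 ± 0.0862 to 139.8 ± 14.4 TPM and Acadvl, which starts mitochondrial oxidation of very long-chain fatty acids, from 0.470 ± 0.395 to 87.7 ± 13.2 TPM (adjusted p = 0.0128 and 0.0140, limma). Eno1 (32.0, 16.7 and 20.2 TPM in APOE_L and 795 ± 205 TPM in APOE_H), the ATP synthase gene Atp5b (111 ± 36.4 to 1395 ± 531 TPM) and Gpx4, which reduces lipid peroxides (188 ± 82.0 to 1152 ± 238 TPM), rose too (adjusted p = 0.00625, 0.00610 and 0.00652, limma).

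Snord13 and Rny3, genes for small non-coding RNAs, were lower in APOE_H. Snord13 was at 2357, 1197 and 2297 TPM in APOE_L and listed at 0 in the 3 APOE_H libraries, and Rny3 fell from 671 ± 373 to 6.01 ± 8.95 TPM (adjusted p = 0.00334 and 0.00629, limma). The mitochondrially encoded mt-Atp6 fell from 27488 ± 5031 to 10144 ± 3309.8 TPM (adjusted p = 0.00588, limma). Ddx58, encoding the RNA sensor RIG-I, fell from 2849.6 ± 877 to 495 ± 90.1 TPM (log2 fold change -2.49, SE 0.44, adjusted p = 0.00554, limma). Of the 83 assembled loci called, 73 were lower and 10 higher.

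Of the 16 lists that passed camera, 4 also passed with an estimated correlation. Oxidative stress genes had 8 of 21 higher and 11 adjusted over the list alone, lysosome genes 9 of 23 and 17, glycolysis genes 8 of 21 with 13 higher and 1 lower over the list alone, and fatty acid oxidation genes 5 of 22 and 11. Their camera adjusted p were 9.64e-07, 4.07e-09, 1.85e-06 and 1.74e-05, with adjusted p = 0.00732, 0.0321, 0.0321 and 0.0321 with an estimated correlation. Oxidative phosphorylation genes had 11 of 32 higher and 17 adjusted over the list alone, choroid plexus markers 9 of 10 and 9, and heat shock genes 4 of 11 and 5 (camera adjusted p = 7.06e-09, 1.17e-08 and 0.00103; adjusted p = 0.0584, 0.0918 and 0.0584 with an estimated correlation). Disease-associated microglia genes had 6 of 20 higher, with 11 higher and 1 lower adjusted over the list alone, and complement and antigen presentation genes 4 of 21, with 11 and 2 (camera adjusted p = 3.22e-06 and 0.00103; adjusted p = 0.103 and 0.222 with an estimated correlation). Unfolded protein response genes had 5 of 15 higher and 6 adjusted over the list alone, lipoprotein and cholesterol transport genes 5 of 20 and 9, and cholesterol synthesis genes 3 of 20 and 6 (camera adjusted p = 0.00103, 0.0130 and 0.0162; adjusted p = 0.152, 0.0678 and 0.0794 with an estimated correlation). Adenosine signalling genes had 2 of 7 higher and 2 adjusted over the list alone, endothelial markers 2 of 11 and 2, and interferon genes 2 of 22 higher and 1 lower, with 3 and 1 over the list alone (camera adjusted p = 0.00829, 0.0458 and 0.00829; adjusted p = 0.0584, 0.337 and 0.309 with an estimated correlation). Mitochondrially encoded genes lay lower, with 7 of 12 called and 9 adjusted over the list alone (median -1.12, camera adjusted p = 4.07e-09; adjusted p = 0.144 with an estimated correlation).

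With 1076 genes, 822 higher and 254 lower, this comparison had the most calls of the 8 (limma, Benjamini-Hochberg), and 3834 entries had an unadjusted p under 0.05. Of the 822 higher genes, 658 (80.1%) were under 1 TPM in at least 2 of the 3 APOE_L libraries. The count was 497, 495 and 676 without APOE_L replicate 1, 2 or 3 and 563 and 429 without APOE_H replicate 1 or 3, and 329 among genes at 5 TPM or more in both groups, where 147 were higher and 182 lower. Quantile normalization gave 568 higher and 419 lower and moved the median log2 fold change of all genes from 0.54 to -0.06.

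**Figure D4:**
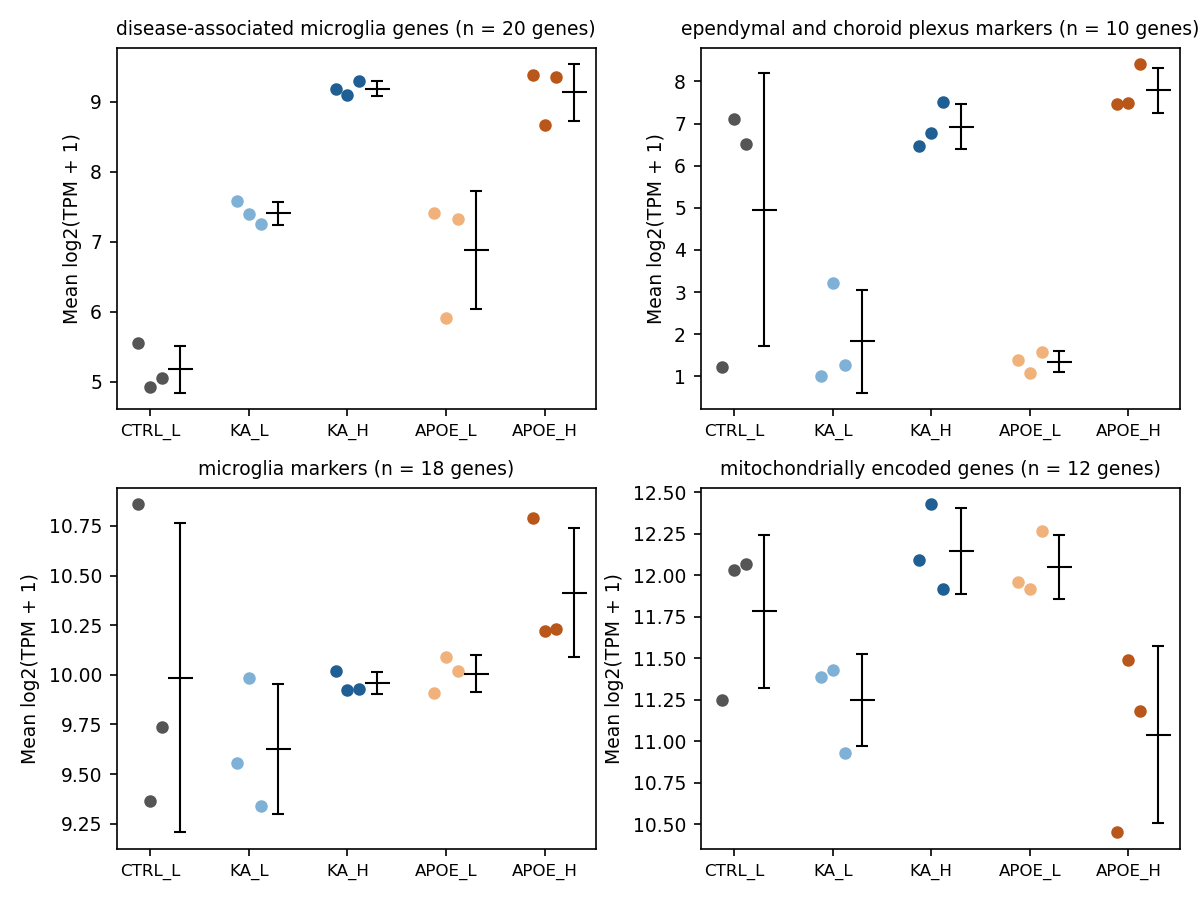
Mean log2(TPM + 1) of the tested members of 4 gene lists in each of the 15 libraries by group, on axes that do not start at 0; points are libraries and black marks the mean ± SD of 3. Disease-associated microglia genes lie lowest in CTRL_L and highest in KA_H and APOE_H, and choroid plexus markers split the CTRL_L libraries.

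Averaged over the letters, 3 genes passed by limma between the APOE condition and KA, and 1440 had an unadjusted p under 0.05. Apoe fell, as given above. Tmem147 rose by 4.09 on the log2 scale (SE 0.53, adjusted p = 0.00621, limma), with 153, 119 and 265 TPM in KA_H and 293, 435 and 294 in APOE_H beside the L values above. Within H alone its log2 fold change was 0.98 and did not pass (adjusted p = 0.799, limma). The averaged value thus rests mainly on the levels near 0 in KA_L, while CTRL_L stood at 52.3, 26.6 and 104 TPM. The processed pseudogene Pdcd5-ps, named after its values were seen, was at 23.01, 20.5 and 23.3 TPM in APOE_L and 40.6, 29.8 and 33.5 in APOE_H, against 1.04 TPM or less in the other 9 libraries (adjusted p = 0.0275, limma). Reads of a processed pseudogene can be shared with its parent gene, so its level is uncertain. Glycolysis and lysosome genes lay higher in the APOE condition, with camera adjusted p = 1.44e-06 and 1.44e-06, with 0 members called in either list and 6 and 3 adjusted over the list alone (adjusted p = 0.0919 and 0.144 with an estimated correlation). Complement and antigen presentation genes (0 of 21 called, 5 adjusted over the list alone), microglia markers (0 of 18, 1), cholesterol synthesis genes (0 of 20, 0) and oligodendrocyte markers (0 of 8, 2) also passed camera with adjusted p = 3.93e-06, 0.00189, 0.0198 and 0.0322 (adjusted p = 0.201, 0.821, 0.144 and 0.144 with an estimated correlation). The count was 16 without KA_L replicate 2 and 7 without APOE_L replicate 1. Quantile normalization gave 2 higher and 7 lower, upper-quartile scaling 2 higher and 4 lower, and rescaling over nuclear protein-coding genes 1 higher and 2 lower, with the median log2 fold change of all genes at 0.07 before and 0.19 after the last.

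The interaction asked whether the difference between APOE and KA was unlike in H and L. It passed for 8 genes, all with a negative value, and 1456 had an unadjusted p under 0.05 (limma). B2m was at 8191 ± 410.2 TPM in KA_L, 24697 ± 5082 in KA_H, 17986 ± 6834 in APOE_L and 11749 ± 2439 in APOE_H (log2 difference -2.14, SE 0.34, adjusted p = 0.0425, limma). Fcer1g, encoding the common Fc receptor gamma chain, was at 2277 ± 798, 6556 ± 1488, 4088 ± 147 and 2699.9 ± 396 TPM in the same order (log2 difference -2.16, SE 0.35, adjusted p = 0.0425, limma). Eif4g3 and mt-Atp6 had log2 differences of -1.59 and -2.30 (adjusted p = 0.0460 and 0.0425, limma), and Churc1 and Tmem147, both near 0 in KA_L, -5.95 and -6.23 (adjusted p = 0.0425 and 0.0460, limma). Whether intronic or genomic background contributes to the Eif4g3 value was not tested. Mitochondrially encoded genes had 12 of 12 negative values, 1 called and 12 adjusted over the list alone (median -1.98, camera adjusted p = 1.99e-26; adjusted p = 0.120 with an estimated correlation). Immediate early genes had 16 of 16 positive values, 0 called and 5 adjusted over the list alone (median 1.85, camera adjusted p = 1.24e-05; adjusted p = 0.161 with an estimated correlation). The count of genes was 22 without KA_L replicate 2. It was 1 without KA_H replicate 2 or APOE_L replicate 2, 2 without KA_H replicate 3, and 0 without KA_L replicate 1 or 3, KA_H replicate 1, APOE_L replicate 1 or 3, or APOE_H replicate 1 or 3. Quantile normalization gave 0 calls and moved the median of all genes from 0.38 to 0.01.

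Between the conditions, the H against L comparisons shared 106 genes higher in H and 20 lower, and 1 gene was called in opposite directions. Independent lists would share 10.1 and 0.638 genes. These comparisons have no library in common, but both take the spread of each gene from the same fit of 15 libraries. Genes of small spread are therefore called more easily in both, and the numbers for independent lists may understate the overlap that chance gives. Across the 17505 tested genes, which are not independent replicates, the fold changes correlated with r = 0.437 and a covariance of 1.55, where simulated unchanged groups gave a covariance of 0.00140. The overlap was between 12 (without KA_H replicate 3) and 107 genes when 1 library was left out. It was 38 or 29 without KA_L replicate 1 or 3, 31 or 60 without KA_H replicate 1 or 2, 75 or 74 without APOE_L replicate 1 or 2, and 69, 79 or 68 without APOE_H replicate 1, 2 or 3.

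Genes called in opposite directions in 2 comparisons that share a KA group were few. Within L, 5 genes fell in KA_L and rose in APOE_L (Tmem147, Psmb5, H2-Aa, Tmem11 and Churc1) and 1 rose and fell (Gm37728), where independent lists would share 0.0274. KA_L enters both comparisons, so their fold changes correlate by chance; r across genes was -0.489 against -0.500 in 100 simulations, and the covariance -1.22 against -0.896. The number was 12, 54 or 28 without KA_L replicate 1, 2 or 3. For H, where the first comparison is between letters and both its groups received KA, 17 genes were higher in KA_H than KA_L and lower in APOE_H than KA_H, among them Apoc2, Fcer1g and mt-Cytb, where independent lists would share 0.529, and 5 were called in the same direction. There r was -0.0871 against -0.499 simulated, and the covariance -0.213 against -0.893. That number was 10 or 9 without KA_L replicate 1 or 3, 11 without KA_H replicate 3, and 11 or 5 without APOE_H replicate 1 or 3. The simulated groups shared 0 genes in either case, but unchanged groups give hardly any calls, so that number says nothing about the excess. Part of it may come from the shared libraries, which with 3 per group could not be split.

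Of the 37 lists, 8 passed camera in no comparison. Some of them passed fry, which does not compare a list with other genes. Astrocyte markers came nearest by camera, with an adjusted p of 0.0788 between KA_H and CTRL_L (6 tested genes, median -0.56, 0 called and 2 lower adjusted over the list alone), and fry gave an adjusted p of 0.00804 there and 0.00327 between KA_L and CTRL_L, both lower. Lipid droplet genes had their smallest camera adjusted p, 0.139, between APOE_H and KA_H (16 genes, median 1.06, 0 called and 0 adjusted over the list alone). For fatty acid synthesis genes and for extracellular matrix genes it was 0.194, both between APOE_H and APOE_L. There 1 of 14 fatty acid synthesis genes was higher and 1 lower, with 1 and 1 adjusted over the list alone, and 3 of 9 matrix genes were higher (Cspg5, Sparc and Gpc4), with 4 adjusted over the list alone. Between APOE_H and APOE_L fry called higher the fatty acid synthesis (adjusted p = 0.0112), extracellular matrix (0.0106), lipid droplet (0.0116) and inhibitory synapse lists (0.00672). The smallest camera adjusted p was 0.363 for glutamate and potassium handling, 0.168 for excitatory synapse genes, 0.228 for inhibitory synapse genes and 0.147 for ion channel genes, with 11, 7, 5 and 3 tested members. In those comparisons 0 of their members were called over all genes, and adjusted over the list alone 1 glutamate and potassium handling gene was higher and 2 lower. Neuron, oligodendrocyte precursor, and mural and fibroblast markers had too few tested members for a list test.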

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

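The interaction tests, the list tests and the counts over other splits of the libraries were planned before the results were seen. Most alternative settings were too. The exceptions were rescaling over entries with a symbol, rescaling over nuclear protein-coding genes and the restriction to genes at 5 TPM or more. The share of shared genes in the CTRL_L libraries had limits set before it was computed, but its rule uses the observed Ttr values. The tests of genomic span, detection, choroid plexus co-variation and the rise of disease-associated microglia genes were chosen after the results were seen. A difference between groups set apart the results of the interaction: the APOE condition and KA differed in H unlike in L. By limma 8 genes passed, with log2 differences of -2.30 for Gm29216, -2.14 for B2m, -2.16 for Fcer1g, -2.30 for mt-Atp6, -5.95 for Churc1, -2.15 for Gm28437, -1.59 for Eif4g3 and -6.23 for Tmem147, and 1456 genes had an unadjusted p under 0.05. Gm29216 and Gm28437 are unprocessed pseudogenes that can share reads with mitochondrial genes, so their levels are uncertain. The difference for Churc1 and Tmem147 rests on levels near 0 in KA_L alone.

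Among the gene lists, mitochondrially encoded genes (median log2 difference -1.98), blood-borne leukocyte markers (-1.39) and red blood cell markers (-4.997) had negative interactions by camera. Adenosine signalling (2.84), heat shock genes (2.19), immediate early genes (1.85), the unfolded protein response (1.64) and lysosome genes (0.78) had positive ones. Their camera adjusted p were 1.99e-26, 0.00967, 0.0107, 0.0107, 0.00586, 1.24e-05, 0.0107 and 0.00967. With an estimated correlation none of the 8 passed (adjusted p = 0.120, 0.161, 0.408, 0.161, 0.161, 0.161, 0.385 and 0.385 in the same order). Over the lists alone 12 of 12 mitochondrially encoded genes were lower, and 5 of 16 immediate early, 3 of 11 heat shock, 2 of 15 unfolded protein response, 1 of 7 adenosine signalling and 1 of 23 lysosome genes higher.

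Other splits of the same libraries were counted for each number of called genes. For the interaction, 1 of 100 splits, the real one, gave as many as 8 genes and the highest other gave 2; for the averaged comparison, 1 of 100, the real one, gave as many as 3 and the highest other 1. The real split stood alone in both, a share under 0.05. Other splits mix APOE with KA libraries, which adds differences such as that of Apoe to the spread. This favours the real split, so the share does not exclude chance for either count. The interaction count itself was fragile. It was 0 with a pseudocount of 5, quantile normalization or no mean-variance trend, 1 with the replicate number as a block, and 0 without KA_L replicate 1 or 3, KA_H replicate 1, APOE_L replicate 1 or 3, or APOE_H replicate 1 or 3. The averaged count was 0 among genes at 5 TPM or more in the groups compared, and 2 to 16 when 1 library was left out. The 6 comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. The real and highest other numbers were 100 and 38 for KA_L against CTRL_L, 260 and 3 for KA_H against KA_L, 66 and 2 for KA_H against CTRL_L, 93 and 34 for APOE_H against KA_H, and 1076 and 0 for APOE_H against APOE_L, the real split being the 1 with as many in each. For APOE_L against KA_L, 4 of 10 splits gave 8 genes or more, and the highest other gave 18.

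The first pattern weighed was the large number of genes that differed between H and L. Genes lower in APOE_H than APOE_L had a median genomic span of 54.4 kb against 19.5 kb in expression-matched random sets and genes lower in KA_H than KA_L 53.8 kb against 18.0 kb, above 100% and 99.9% of 10000 sets, while the higher genes were shorter than matched sets (14.1 against 20.4 kb and 9.16 against 22.2 kb). Intronic or genomic background in the L libraries may therefore account for part of the lower calls, and the span bias runs through the higher calls as well. Fewer entries at 1 TPM or more in L (entries above 0 were more numerous there, 18944 in APOE_L against 17645 in APOE_H) could not explain all of the higher calls, since 147 genes were higher among the 7060 with a mean of 5 TPM or more in both groups, 97 of them at 5 TPM or more in each of the 6 libraries, although 182 were lower there and the excess of higher calls turned round. What L and H denote is not given in the sources used here, and no biological explanation of the letters was tested.

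The second pattern was the choroid plexus markers, higher in H. For deviations from the group means in the 12 libraries other than CTRL_L, which leave out the difference between H and L, their median pairwise Spearman rho was 0.434 (10 genes), where 95% of 2000 expression-matched sets lay at or below 0.1305, so choroid plexus cells or their RNA in some libraries are a candidate explanation. Ttr, the most abundant of them, was at 54.1, 20666 and 10235 TPM in the 3 CTRL_L libraries, a spread within 1 group. Of the 106 genes higher in both H against L comparisons, 54 (50.9%) were higher in CTRL_L replicates 2 and 3 than in replicate 1. That share lies between 90% and 33%, the limits set before the share was computed, though the rule itself uses the observed Ttr values in CTRL_L. This share judges the genes as 1 set and cannot sort single genes. The set held Ttr, Folr1, Kcnj13 and Enpp2 of the choroid plexus list, and also Cd74, H2-Aa, Lyz2 and Ctsb of other lists. For the set as a whole a choroid plexus source and another therefore cannot be told apart.

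The third pattern was the rise of disease-associated microglia genes. Without CTRL_L replicate 1, the CTRL_L library low in choroid plexus transcripts, the list kept a camera adjusted p of 4.57e-32 (median 3.21) between KA_H and CTRL_L while the choroid plexus list had 0.842 (median -0.10), which argues against choroid plexus RNA as the cause. That test does not bear on other cell types. Leukocyte markers also had a higher mean log2 level in KA_H (4.80 ± 0.02) than in CTRL_L (2.17 ± 0.63). In APOE_H the disease-associated microglia list without Apoe lay 0.41 above KA_H (95% interval -0.46 to 1.28, 19 genes), which argues against its level in H depending on Apoe by more than 1 on the log2 scale. KA_H and CTRL_L differ in both KA and the letter, and the list without Apoe was higher at each step. Between the letters after KA, it lay 1.77 higher in KA_H than KA_L (95% interval 0.89 to 2.64). The full list did not pass there with an estimated correlation. There was no untreated H group, so how far the letter alone accounts for the difference stays open. Within L, the 19 genes without Apoe lay 2.21 higher in KA_L than CTRL_L (95% interval 1.34 to 3.08), but 16 of the 20 list genes did not pass (median 1.25), the list was not called with an estimated correlation (adjusted p = 0.217), and choroid plexus markers moved as well (median -3.34).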

How the results depend on the processing

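The numbers of called genes moved with many settings, and the rescaling over entries with a symbol, the rescaling over nuclear protein-coding genes and the restriction to genes at 5 TPM or more in the groups compared were chosen after seeing the data. Numbers of called genes stayed within 1.5 times in 92 of 180 alternatives, numbers of called lists in 99 of 116 and overlaps in 25 of 48. Of 8959 values for named genes 7610 kept direction and side of the threshold, 1226 lost their call, 119 gained one and 4 reversed; of 1221 list results 995 kept both, 224 lost their call and 2 reversed. Cd14 (not called) in KA_H against KA_L was -0.12 without KA_L replicate 1 and -0.17 without KA_L replicate 3, Ptgs2 there -0.34 without KA_H replicate 3, and Folr1 in KA_H against CTRL_L -0.31 without CTRL_L replicate 1. Over the libraries left out they lay between -0.17 and 0.91 (Cd14), -0.34 and 0.99 (Ptgs2) and -0.31 and 3.96 (Folr1). The reversed lists, both in KA_H against CTRL_L, were the mitochondrially encoded genes under quantile normalization (adjusted p = 0.937) and the ependymal and choroid plexus markers without CTRL_L replicate 1 (0.842, against 0.000271 without CTRL_L replicate 2). The cause was not tested. Read depth is not given in the sources used here, so the limit that it sets on low genes was not measured.

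Counts are given in the order KA_L against CTRL_L, KA_H against KA_L, KA_H against CTRL_L, APOE_L against KA_L, APOE_H against KA_H, APOE_H against APOE_L, averaged and interaction, where they were 100, 260, 66, 8, 93, 1076, 3 and 8 genes and 8, 18, 16, 5, 11, 16, 6 and 8 lists. With no filter on low values they were 50, 100, 33, 13, 4, 538, 8 and 3 genes. Restricted to genes at 5 TPM or more, which tests fewer genes, they were 2, 106, 8, 0, 4, 329, 0 and 0. The other settings are given where a count moved over 1.5 times. Upper-quartile scaling gave 62 genes in KA_L against CTRL_L, 394 in KA_H against KA_L, 139 in KA_H against CTRL_L, 6 averaged and 24 in the interaction. Fitting only the groups compared, which leaves fewer libraries to estimate the spread, gave 0, 3, 3, 1, 0 in the first 5 comparisons, 6 averaged and 18 in the interaction. Array weights gave 21 in KA_L against CTRL_L, 30 in KA_H against CTRL_L, 4 in APOE_L against KA_L, 255 in APOE_H against KA_H, 2024 in APOE_H against APOE_L, 11 averaged and 14 in the interaction.

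A pseudocount of 5 gave 32 genes in KA_H against CTRL_L, 5 in APOE_L against KA_L and 0 in the interaction. It gave an overlap of 73 genes between the H against L comparisons (126 before) and 9 opposite calls in H (17 before). Quantile normalization gave 25 genes in APOE_H against KA_H, 9 averaged, 0 in the interaction and 5 opposite calls in H. The stricter filter gave 43 in APOE_H against KA_H and 13 in the interaction, and no mean-variance trend 32 in APOE_H against KA_H, 7 averaged and 0 in the interaction. Rescaling over nuclear protein-coding genes gave 55 genes in APOE_H against KA_H and 8 opposite calls in H, with 6 lists in APOE_H against KA_H, 8 in APOE_H against APOE_L and 5 in the interaction. With an estimated inter-gene correlation 0, 0, 2, 0, 0, 4, 0 and 0 lists passed. The fry rotation test gave 5 lists in KA_L against CTRL_L, 10 in KA_H against CTRL_L, 0 in APOE_L against KA_L and 3 in the interaction. Except for the filters and the libraries fitted, the cause was not tested.

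Leaving out 1 library at a time gave 66 to 232, 38 to 300, 17 to 52, 8 to 68, 50 to 120, 429 to 766, 2 to 16 and 0 to 22 genes and 7 to 11, 13 to 17, 13 to 17, 3 to 7, 8 to 13, 14 to 18, 4 to 7 and 6 to 10 lists, in the same order. In APOE_L against KA_L the lists numbered 3 without KA_L replicate 3 and 3 without APOE_L replicate 1. The averaged log2 fold change of Apoe lay between -10.53 and -9.46, the overlap between 12 and 107 genes, opposite calls in L between 4 and 54 and opposite calls in H between 5 and 17.

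The replicate numbers gave little sign of pairing the libraries. Deviations from the group means correlated with a mean of 0.00432 between libraries of the same number (-0.0263 to 0.0365, 30 pairs, 0 above 0.1) and -0.00215 between others. Still, 10 of 15 libraries correlated best with their own number, more than an even choice among the numbers gives, so pairing is not excluded. With the replicate block 19 genes were called in KA_H against CTRL_L, 4 in APOE_L against KA_L, 61 in APOE_H against KA_H and 1 in the interaction, with 3 opposite calls in L.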

Other observations

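Lipid droplet genes, which bear on lipid storage, varied widely in level. Of the 24 on the list, 16 passed the expression filter, 2 reached 1 TPM in each of the 15 libraries and 4 stayed under 1 TPM in all of them. The 2 were Mgll, a monoglyceride lipase gene (2.92 to 166 TPM), and Hsd17b11 (4.65 to 60.4 TPM), and Lipe, the hormone-sensitive lipase gene, reached 1 TPM in 13 libraries. Plin2, encoding the droplet coat protein perilipin 2, ran from 0.13 to 184 TPM and reached 1 TPM in 13 of the 15 libraries. Plin1 did not exceed 0.23 TPM and Plin3 37.5 TPM in any library. Hilpda, which inhibits triglyceride lipolysis, was listed at 0 in 8 libraries and was at 84.5 TPM at most. Abca1, the cholesterol exporter gene, was present throughout, from 30.5 to 129 TPM, and Fabp5, a fatty acid binding protein gene, reached 255 TPM.

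Markers of other brain cells were uneven as well. Mbp, a myelin protein gene, ran from 4.19 to 143 TPM, while Mog was listed at 0 in all 15 libraries. The neuronal genes Rbfox3 and Snap25 were listed at 0 in 13 and 10 libraries, the latter reaching 8.45 TPM. Aldh1l1, an astrocyte enzyme gene, was listed at 0 in 10 libraries and did not exceed 3.94 TPM.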
